A study of Homo sapiens with 6 samples.

How the data were processed

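H3K4me3 and H3K27me3 were measured by ChIP-seq in H1 human embryonic stem cells (hESC) and in trophoblast stem cells derived from them (hTSC), with 1 library per mark and cell type. The labels also list 2 input samples, which were not analysed here. Per the submitters' processing notes, Bowtie2, SICER and deepTools and the builds hg38 and GRCh38 were used, with no version, role or setting stated. The labels give a separate antibody for each mark, while the protocol text names antibodies to H3K27me3 only. Each deposited file lists the called islands of 1 library by position with a value that is here called a score, since the authors do not name its unit; it ran from just above 2 to a cap of 1000 and was used only to rank or filter islands within a library. All islands were whole multiples of 200 bp. The smallest gap between islands was 400 bp for H3K4me3 and 800 bp for H3K27me3. The files hold no read counts, so depth is unknown and no interval or detection limit was computed from it. An island that was not called is not evidence that a mark was absent.

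Promoters were placed with the RefSeq gene table for GRCh38, which gives the outer ends of each gene without strand or transcripts. Of the ends of each of 19821 coding genes, the one with more H3K4me3 within 1 kb to either side, added over both cell types, was taken as the promoter. This departs from the transcription start sites planned, which need strand. It chose 1 end for 15266 genes; both ends were used for 4334 genes without H3K4me3 at either end and for 221 ties. As a check, 529 genes with a noncoding transcript starting within 2 kb of one end, whose name gives the direction, could be decided, and the choice was right for 525 (99.2%). This share covers such genes only and need not hold for the others. An end beside another gene's H3K4me3 can be chosen wrongly, as may be the case at EXOC6. Promoters inside a gene are missed, as at TP63. A promoter carried a mark if any island overlapped its 2 kb window, and H3K27me3 coverage was the percent of the 20 kb around it that islands covered. H3K4me3 width was that of the widest island over the promoter, and log2 width ratios compared hTSC with hESC. In the gene lists, genes in island-free stretches of 100 kb or more were treated as unmeasured; the 1131 such genes stayed in the counts and mean coverage over all promoters, except where 18690 promoters are named. Chromosome Y genes and XIST were left out.

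Islands were called shared if they overlapped an island of the other cell type by 1 base, and the share was set beside 100 rotations of the islands along each chromosome, in place of the shuffling planned. With 1 library per group no test between groups is possible and no p-values were computed. Gene lists were compared with 10000 random lists of the same size, drawn from all 19821 coding genes and matched in 10 bins on mean coverage over both cell types, with genes at 0 in both in a bin of their own; a percentile says where the list's mean difference lay among them, and outside means outside the middle 95%. Random lists describe genes, which are not independent replicates.

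The gene lists, the rule for named genes, the comparisons and most alternatives were chosen before the data were examined. The lists were pluripotency, trophoblast stem cell and cytotrophoblast, syncytiotrophoblast, extravillous trophoblast, amnion, neuroectoderm, mesoderm, endoderm, blood and endothelium, stromal and fibroblast, germline, imprinted, housekeeping, polycomb and trithorax regulators, WNT, TGF-beta, BMP and FGF signalling, and HOX clusters. Families taken by symbol were olfactory receptors, ZNF zinc fingers, clustered protocadherins, keratins, replication-dependent histones, SOX, forkhead, T-box, PAX, and LHX and LMX genes. Named genes were list members, the 10 genes with the largest H3K27me3 coverage difference in each direction (ties ordered by score per kb), and the 10 with the widest H3K4me3 island in one cell type only, in each. To these came the 5 largest log2 width ratios in each direction and, among promoters with both marks in hESC, the 5 largest H3K27me3 differences in each direction. Noncoding genes, the TP63 region and the split of ZNF genes by chromosome were chosen after the data were seen.

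The alternatives were the upper 50% of islands by score per kb or by score, equal covered length by either, islands of 1 kb or more, an overlap of 50%, islands merged within 1 kb, other windows, both gene ends, the whole gene, unmatched random lists, and leaving out dense blocks or chromosomes 2 and 20. Equal covered length trims the library that covers more of the genome. Dense blocks are 1 Mb windows of which H3K4me3 islands of either cell type cover 20% or more. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The covered length of all 19821 windows equalled that from bedtools 2.31.1 on simulated islands. In simulated genes with H3K4me3 at their own promoter, the end was chosen correctly for 14741 of 15121 (97.5%). Simulated genes without it, where a neighbour's island can decide, were not counted. Of 50 simulated lists of 30 genes, 4 lay outside the middle 95% with no shift, 28 with a shift of -10 points and 49 with -20 points. The H3K27me3 differences were first shuffled over genes, which removes their link with coverage and the islands shared by neighbouring genes. These rates need not hold for the real lists.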

Results

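Histone H3 trimethylated at lysine 4 (H3K4me3), a mark of promoters that are active or poised, and histone H3 trimethylated at lysine 27 (H3K27me3), the mark of polycomb repression, were profiled by ChIP-seq. The cells were human embryonic stem cells (hESC) of the H1 line and human trophoblast stem cells (hTSC) derived from H1. Trophoblast stem cells are the proliferating precursors of the placental trophoblast, which forms the hormone-secreting syncytiotrophoblast and the invasive extravillous trophoblast. The design asked how the sites of both marks differ between these cell types. Each mark was represented by 1 library per cell type, 4 libraries in all, so the differences have no replicate check and no p-values are given. The deposited lists hold called intervals of enrichment (islands) and no read counts, so the depth of each library is unknown. In hESC, 46909 H3K4me3 islands covered 111 Mb and 47314 H3K27me3 islands covered 230.1 Mb. In hTSC, 62687 H3K4me3 islands covered 148 Mb and 59775 H3K27me3 islands covered 525 Mb. The covered length was thus 1.33 times as large in hTSC for H3K4me3, with 1.34 times as many islands and a median width of 1.8 kb in both cell types. For H3K27me3 it was 2.28 times as large, with 1.26 times as many islands and median widths of 3 kb in hESC and 5.4 kb in hTSC.

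Genes of the trophoblast stem cell and cytotrophoblast list lay under H3K27me3 in hESC and were largely free of it in hTSC. H3K27me3 overlapped the promoters of 23 of the 38 listed genes in hESC and of 5 in hTSC, with 18 in hESC only and 0 in hTSC only. Of the 22 genes with both marks in hESC, 17 had H3K4me3 alone in hTSC. At GATA3, which encodes a transcription factor that specifies trophoblast, H3K27me3 covered 100% of the 20 kb around the promoter in hESC and 0% in hTSC. The hESC island spanned 39 kb (hg38, chromosome 10, 8030601 to 8069600) and reached from upstream of GATA3 into the gene body. The H3K4me3 island over the GATA3 promoter was 24.2 kb wide in hESC and 30.4 kb in hTSC. TFAP2A, TFAP2C and GATA2, further transcription factors of the trophoblast network, had H3K27me3 coverage of 100%, 51% and 87% in hESC and 0% in hTSC. The homeobox genes MSX2 and DLX3 went from 92.9% and 85.9% coverage to 0%.

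Wider H3K4me3 went with this. Among the 30 trophoblast stem cell genes with H3K4me3 in both cell types, the island was wider in hTSC at 25 and narrower at 5. The median width over marked genes of the list was 5 kb in hESC and 9.8 kb in hTSC, against 3.2 and 3.8 kb over all promoters marked in both. Width was 3.6 kb in hESC and 21.4 kb in hTSC at OVOL1, an epithelial repressor, 2.4 and 13.6 kb at the nuclear receptor gene PPARG, and 2.4 and 9.2 kb at KRT7, a trophoblast keratin. At CDH1, which encodes E-cadherin, it was 2.8 and 10.6 kb, with no H3K27me3 island in either cell type. H3K4me3 was called in hTSC only at 6 members: ELF5 (3.8 kb), VGLL1 (11.8 kb), PAGE4 (4.8 kb), ZNF750 (7.2 kb), SIGLEC6 (10 kb) and S100P (6 kb). TFAP2B went the other way, with an 11.2 kb H3K4me3 island in hESC, none in hTSC, and H3K27me3 coverage of 90.8% and 86.2%. CDX2, DLX5 and DLX6 kept both marks, with H3K27me3 coverage in hTSC of 67%, 94% and 100%. The list's mean H3K27me3 coverage was 41.1% in hESC and 11.0% in hTSC. This difference of -30.1 percentage points lay below all 10000 random lists of genes matched on mean coverage (percentile 0), and the H3K4me3 difference of 13.4 points lay at percentile 100. Merging islands less than 1 kb apart turned the width difference of TFAP2A to -0.048 on the log2 scale, since further hESC islands were then joined to the one at the promoter.

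**Figure D1:**
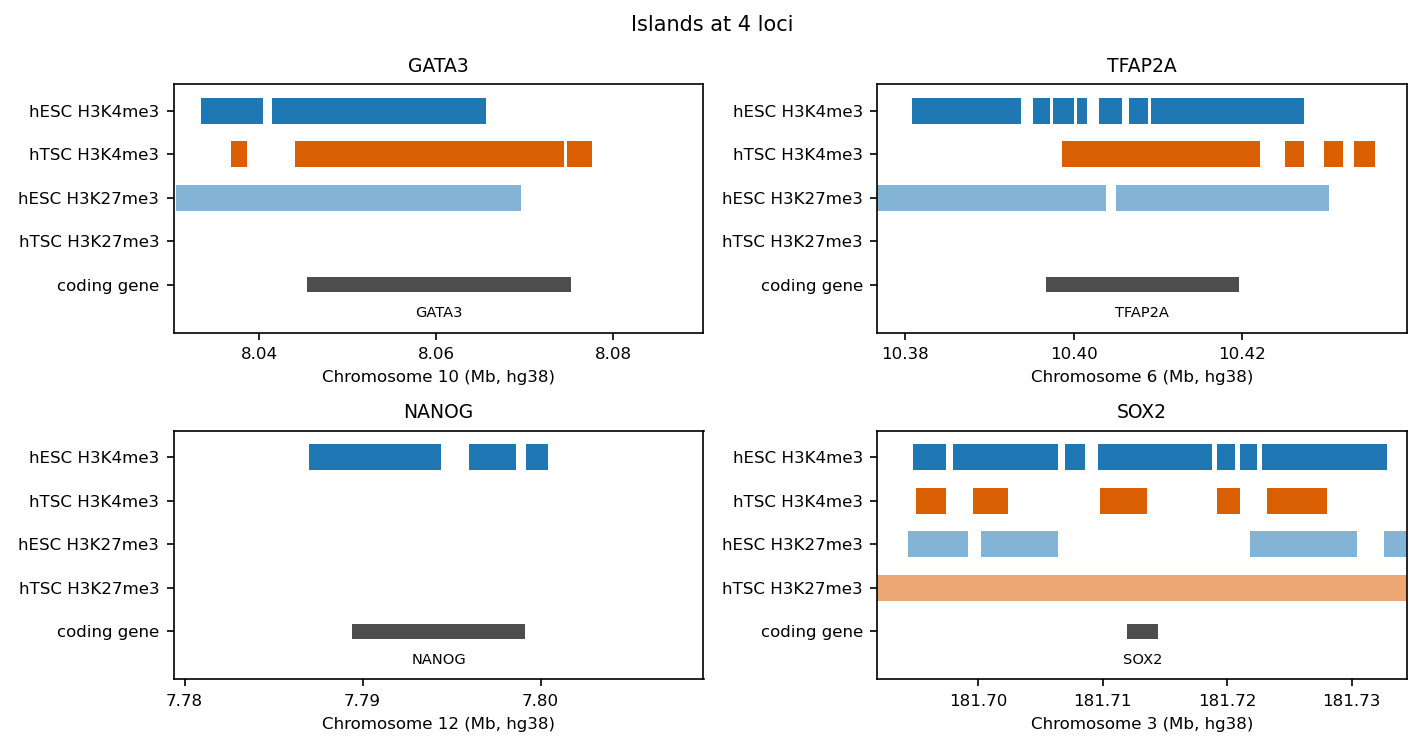
Called islands of both marks in hESC (blue) and hTSC (orange) around GATA3, TFAP2A, NANOG and SOX2, drawn to scale on hg38 coordinates in Mb, with the coding gene in grey; islands that run past a panel's edge are clipped there. The H3K27me3 island over GATA3 in hESC is 39 kb wide and has no counterpart in hTSC, while SOX2 lies inside a 50.2 kb H3K27me3 island in hTSC.

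Genes of the syncytiotrophoblast, a differentiated cell type, also carried H3K4me3 in hTSC. Of 26 listed genes, H3K4me3 was called at 10 in hESC and 20 in hTSC, with 13 in hTSC only and 3 in hESC only. The 13 included CGA (5.4 kb in hTSC), the common subunit of the glycoprotein hormones, GCM1 (13.8 kb), a regulator of trophoblast fusion, and the endogenous retroviral envelope genes ERVW-1 (10 kb) and ERVFRD-1 (8.4 kb), whose products fuse cells. HOPX (10.8 kb), CYP19A1 (12.4 kb), which encodes aromatase, and LEP (7.4 kb), which encodes leptin, were among them too. At SDC1, which encodes a surface proteoglycan, the island was 5 kb wide in hESC and 23 kb in hTSC. Mean H3K27me3 coverage of the list was 24.3% in hESC and 3.62% in hTSC (percentile 0.02 of random lists), and the mean H3K4me3 coverage of the promoters was 26% and 64.2% (percentile 100). Without 1 Mb blocks dense in H3K4me3 islands, the H3K27me3 difference was -11.7 points and fell within the middle 95% of random lists. The CGB and PSG genes are near-identical copies, so their values are uncertain. PSG1, PSG3 and PSG5 had 100% H3K27me3 coverage in hESC and 0% in hTSC.

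The extravillous trophoblast list did not stand apart. H3K27me3 was called at 10 of 15 measured genes in hESC and at 5 in hTSC, and mean coverage was 23.7% and 14.6% (percentile 13.1), with differences from -24.0 points (4 kb window) to 0.379 points (100 kb) over the alternatives. Single members differed widely. ASCL2, MMP2 and ITGA5 had coverage of 55%, 57.9% and 66.3% in hESC and 0% in hTSC, whereas PRG2 had 10.1% and 95%, PAPPA2 0% and 43%, and ITGA1 0% and 50.4%. At MMP2 the difference depended on the window, since 100 kb around the promoter gave 13.2 points more coverage in hTSC. Among 10 amnion genes, included because amnion resembles trophoblast in several markers, mean coverage was 47.9% and 44.9% (percentile 14.7), a difference that was -24.0 points at equal covered length by score per kb and 1.40 points over whole genes. TBX3 and MEIS2 went from 100% and 96% to 0%, ISL1 had 100% in both, and GABRP and ITGB6 went from 0% to 86% and 91.6% while H3K4me3 islands of 3 and 4 kb were called in hTSC only.

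Pluripotency genes showed less H3K4me3 in hTSC. Of 29 measured genes, 26 had H3K4me3 in hESC and 19 in hTSC, and the 7 in hESC only were NANOG (7.4 kb), DPPA4 (14.6 kb), the NODAL co-receptor gene CRIPTO (14.2 kb, also called TDGF1), LEFTY1 (2.8 kb), LEFTY2 (1.4 kb), GDF3 (2 kb) and SALL2 (7 kb). At 18 of the 19 genes marked in both the island was narrower in hTSC, and the median width over marked genes was 9.2 kb in hESC and 4 kb in hTSC. DNMT3B, a de novo DNA methyltransferase gene, had widths of 13 and 5.8 kb, and the homeobox gene OTX2 25.2 and 5.8 kb. LIN28A was the exception, at 12.4 and 12.8 kb. Mean H3K4me3 coverage of the promoters was 81.4% in hESC and 57.8% in hTSC, a difference below all random lists (percentile 0). POU5F1 could not be measured, because it lies in a 2556 kb stretch of chromosome 6 without islands of either mark in any library.

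H3K27me3 lay over part of the pluripotency list in hTSC and not over the rest. SOX2 had coverage of 23% in hESC and 100% in hTSC, where an island of 50.2 kb (hg38, chromosome 3, 181688601 to 181738800) enclosed the gene. PRDM14 went from 10% to 100%, ZIC3 from 0% to 69.6%, SFRP2 from 5.59% to 96% and PODXL from 0% to 30%. NANOG, DPPA4 and GDF3 had 0% in both cell types. The list had H3K27me3 at 8 promoters in hESC and 13 in hTSC, and mean coverage of 18.9% and 31.8%. This lay within the middle 95% of random lists (percentile 92.8), but outside it for a window of 4 kb, with a difference of 16.1 points, and with random lists that were not matched (percentile 98.4).

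**Figure D2:**
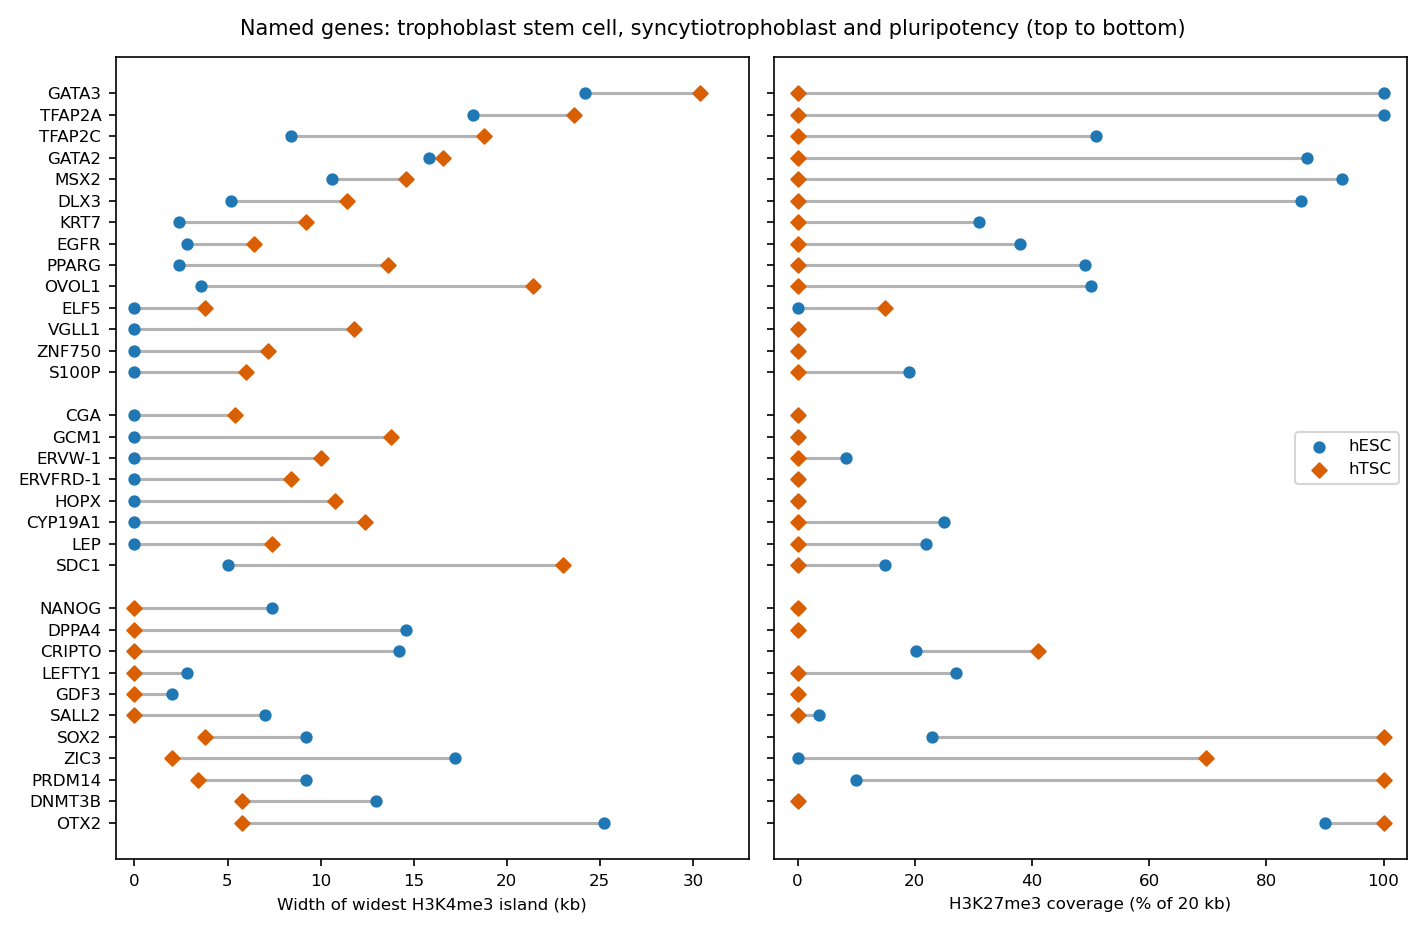
Width of the widest H3K4me3 island over the promoter in kb (left) and percent of the 20 kb around the promoter covered by H3K27me3 islands (right) for genes of 3 lists, with hESC as blue circles and hTSC as orange diamonds; a width of 0 means that no island was called. GCM1 goes from 0 to 13.8 kb and NANOG from 7.4 to 0 kb of H3K4me3, and SOX2 goes from 23% to 100% H3K27me3 coverage.

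Regulators of the embryonic germ layers carried both marks in hESC and mostly kept H3K27me3 in hTSC, with shorter H3K4me3 islands. All 26 neuroectoderm genes had both marks in hESC, and 25 had both in hTSC; the exception, LHX2, had H3K27me3 coverage of 100% in hESC and 0% in hTSC. The H3K4me3 island was narrower in hTSC at 25 of the 26, with a median width of 11.7 kb in hESC and 4.7 kb in hTSC. At the neural regulators PAX6, SOX1 and SIX3 the widths were 26.2, 22.4 and 22.6 kb in hESC and 5.2, 3.4 and 2.6 kb in hTSC. Mean H3K27me3 coverage was 94.2% and 84.1% (percentile 0.01), and 14 genes were fully covered in each cell type. A gene at 100% in hESC cannot gain coverage, so lists near that ceiling lie low among random lists in part by construction. With 4 kb around the promoter the list lay within the middle 95% of random lists, and with 100 kb its coverage was higher in hTSC by 21.5 points.

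Among 23 mesoderm genes, 21 had both marks in hESC and 14 in hTSC. H3K4me3 was called at 22 and 18 genes, and the promoters' mean H3K4me3 coverage of 87.8% in hESC and 67.2% in hTSC gave a difference below all random lists. TBXT, the brachyury gene, had a 9.2 kb island in hESC and 1 kb in hTSC, and EOMES 13.2 and 3.2 kb. GATA4, a heart and endoderm regulator, had a 6 kb island in hESC and none in hTSC, with H3K27me3 coverage of 72.7% and 100%, although over the whole gene the difference was -8.48 points. PITX2 had H3K4me3 of 8.2 kb and H3K27me3 coverage of 100% in hESC, and no H3K4me3 with 19.1% in hTSC. Mean H3K27me3 coverage of the list was 74.7% and 63.1% (percentile 0.13). The call ended with a 4 kb window (-20.3 points, percentile 6.64) and with both gene ends (-0.178 points), and the direction turned over 100 kb (15.5 points) and whole genes (0.0292 points). The 18 measured endoderm genes had mean coverage of 57.3% and 58.4% (percentile 8.76), a difference whose sign varied with the processing, from -11.2 points (4 kb window) to 27.5 points (100 kb). It moved outside the random lists for the upper 50% of islands by score per kb (-5.39 points) and at equal covered length by score (-8.99 points). GATA6 and SOX7 went from 100% and 68.6% to 0% with H3K4me3 in place, while CXCR4 went from 34% to 100%. The H3K4me3 island was narrower in hTSC at 12 of 13 endoderm genes marked in both, such as ONECUT1 with 24.2 and 4 kb.

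**Figure D3:**
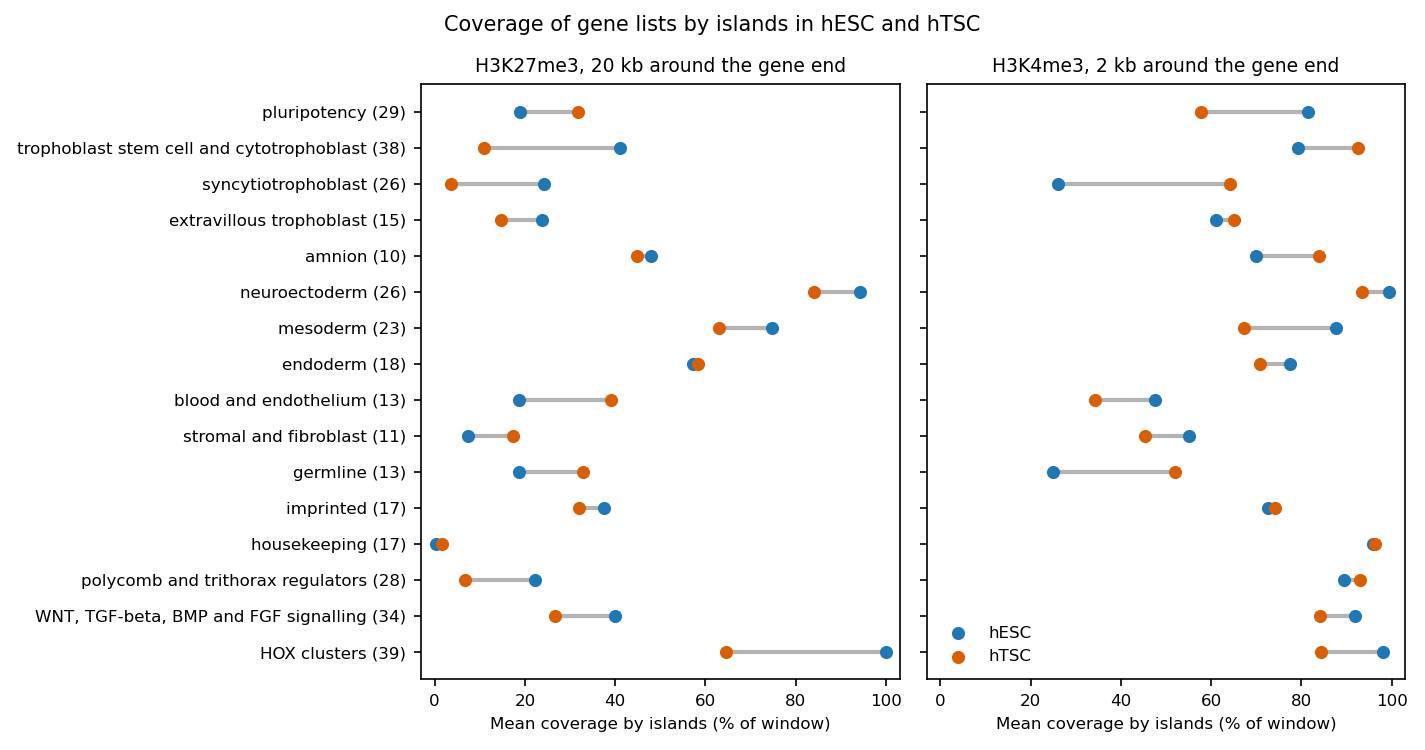
Mean percent of the window covered by islands for the fixed gene lists, with the number of measured genes in brackets; the left panel gives H3K27me3 over 20 kb and the right panel H3K4me3 over 2 kb, with hESC in blue and hTSC in orange, 1 library each. H3K27me3 coverage is 41.1% in hESC and 11.0% in hTSC for trophoblast stem cell genes, and 100% and 64.5% for HOX genes.

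The 4 HOX clusters, which encode the regulators of body axis patterning, parted in hTSC. All 39 HOX genes had 100% H3K27me3 coverage in hESC. In hTSC, all 11 HOXA and all 9 HOXD genes remained at 100%, while the mean was 42.6% over 10 HOXB genes and 10.1% over 9 HOXC genes. HOXC4 to HOXC10 had 0%, and HOXC11, HOXC12 and HOXC13, at one end of the cluster, had 23%, 22% and 45.9%. The single hESC island over the HOXC cluster spanned 232 kb (hg38, chromosome 12, 53911001 to 54143000), against 3 islands of 15.2, 4.4 and 4.6 kb in hTSC. Within HOXB the coverage was 0% at HOXB1, HOXB2 and HOXB4, 10.6% at HOXB3, 38.9% at HOXB5, and 100% at HOXB9 and HOXB13. H3K4me3 was called at 39 HOX genes in hESC and 37 in hTSC, so 10 of the genes without H3K27me3 in hTSC had H3K4me3 alone there. The list's mean was 100% in hESC and 64.5% in hTSC (percentile 0). Every HOX gene stood at 100% in hESC, so the list's difference could not be positive. The middle part of its random lists ran from 5.43 to 34.7 points, so an unchanged HOX list would also have lain below it. The percentile therefore cannot tell a loss from no change here, and only the coverage values describe the difference. The score is capped, so wide islands rank low by score per kb. At equal covered length by score per kb all 9 HOXD genes were at 0% in hTSC and the list's difference was -62.7 points, whereas by score all 9 were at 100%. Keeping only the upper 50% of islands by score per kb removed H3K27me3 from HOXA and HOXC in hESC and turned the direction to 12.2 points.

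**Figure D4:**
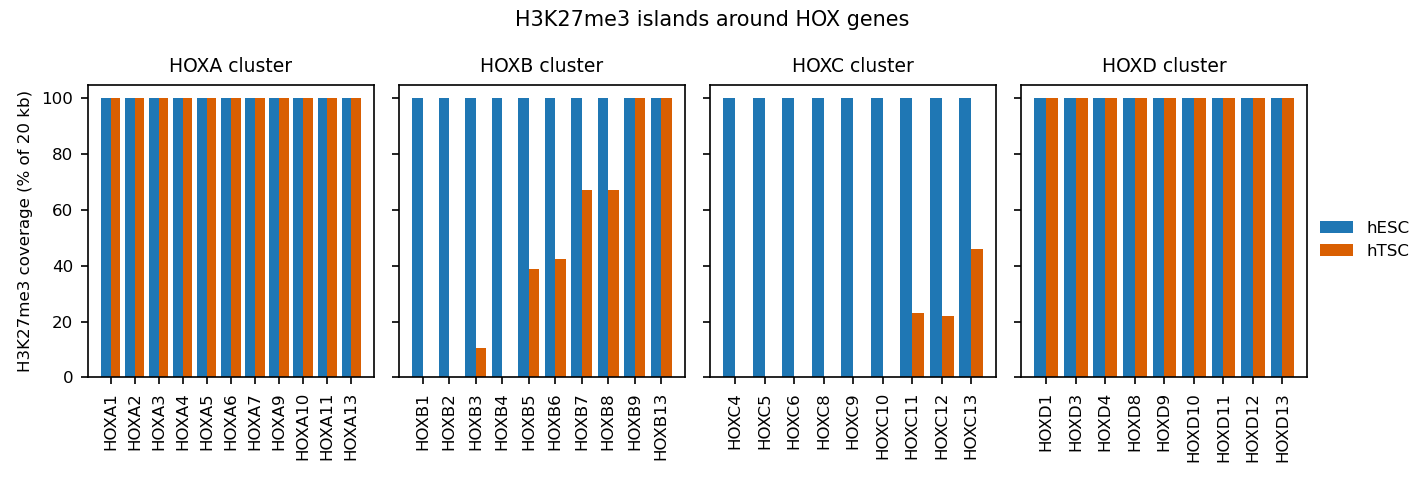
Percent of the 20 kb around each HOX promoter covered by H3K27me3 islands in hESC (blue bars) and hTSC (orange bars), with genes in order of their number in each of the 4 clusters and 1 library per bar. All bars stand at 100% for HOXA and HOXD, while HOXC4 to HOXC10 are at 0% in hTSC.

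Signalling and chromatin regulator genes also had less H3K27me3 in hTSC, with exceptions. Of 34 measured WNT, TGF-beta, BMP and FGF genes, H3K27me3 was called at 27 in hESC and 14 in hTSC, and 15 went from both marks to H3K4me3 alone. BMP4 and WNT7A went from 92% and 91% coverage to 0%, and LEF1 from 100% to 41%. The reverse held for FGF2, with 0% in hESC and 68.4% in hTSC, and BMP2, with 31% and 100%. The list's mean was 40.0% and 26.7% (percentile 0.31). The list lay within the middle 95% of random lists over 4 kb, over whole genes and at equal covered length by score per kb (not by score), and its difference was 0.193 points over 100 kb. Of 28 measured polycomb and trithorax regulators, 11 had H3K27me3 in hESC and 6 in hTSC, with mean coverage of 22.3% and 6.68% (percentile 0.09). TET2, which encodes a 5-methylcytosine dioxygenase, went from 78% to 0%, and the polycomb gene CBX8 from 100% to 25.4% with H3K4me3 islands of 28.4 and 5.4 kb. JARID2, which encodes a cofactor of polycomb complex PRC2, had no H3K27me3 in either cell type and H3K4me3 islands of 18.8 and 7 kb.

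The control lists came out as follows. All 17 measured housekeeping genes, among them ACTB and GAPDH, had H3K4me3 and none had H3K27me3 at the promoter in either cell type. Olfactory receptor genes, which are mostly silent outside the nose and were chosen as a control expected to lack both marks, did carry them. Of 325 measured receptor genes, 78 (24%) had H3K4me3 in hESC and 25 (7.69%) in hTSC, and 125 (38.5%) had H3K27me3 in hESC and 121 (37.2%) in hTSC. Both marks were called at 74 receptor genes in hESC and 11 in hTSC. Their H3K27me3 coverage was 33.6% and 25.4% (percentile 0), but without 1 Mb blocks dense in H3K4me3 islands the difference was 2.88 points, higher in hTSC, and with a 4 kb window it lay within the middle 95% of random lists (-6.80 points, percentile 84.8). Among the upper 50% of islands by score, H3K4me3 was at 14 receptor genes in hESC and 11 in hTSC, and H3K27me3 at 113 and 74. Markers of cell types that could be mixed into a culture lay within the middle 95% of random lists. The 13 measured blood and endothelium genes had mean H3K27me3 coverage of 18.8% in hESC and 39.0% in hTSC (percentile 83.4) and H3K4me3 at 7 promoters in each, both marks lying outside that range against lists that were not matched. The 11 measured stromal genes had 7.38% and 17.3% (percentile 87.3) and H3K4me3 at 7 and 6 promoters, with H3K27me3 differences from 0.0727 points (4 kb window) to 13.04 points (both gene ends), the latter just outside.

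Over all coding genes, H3K4me3 was called at nearly the same promoters in both cell types. Of 19821 promoters, 14588 had H3K4me3 in hESC and 14751 in hTSC, with 13852 in common, 736 in hESC only and 899 in hTSC only. The widest islands among promoters marked in hTSC only were at ZNF217 (22.2 kb), a transcriptional repressor gene, TACC2 (21.8 kb), SLC7A2 (15.2 kb), MSMB (15 kb) and TGM2 (14.8 kb). Next came FAM178B (14 kb), CCIN and GCM1 (13.8 kb each), and OLR1 with its neighbour TMEM52B (13.2 kb). The MSMB island ended before the gene's start and covered 14.4% of the promoter window, and no island touched the gene. In hESC, H3K4me3 outside the promoter window covered 14.4% of the 20 kb around MSMB, 34% around FAM178B and 37% around ZNF217. Strand is unknown, so a chosen end need not be the promoter. Promoters marked in hESC only were led by the beta-defensin genes DEFB118 and DEFB119 under a common 28.8 kb island, DEFB123 (18.2 kb) and EXOC6 (18 kb). The EXOC6 island is the one over its neighbour CYP26C1, so the chosen end of EXOC6 may not be its promoter. ONECUT3 (16.8 kb), TTC34 (15.2 kb), HOXB6 (15 kb), DPPA4 (14.6 kb), CRIPTO (14.2 kb) and DEFB116 (14 kb) came next. The defensin islands had scores of 175 (DEFB118 and DEFB119), 145 (DEFB123) and 66.2 (DEFB116). These lie above the library's median of 31.5, but the other genes named here were at the cap of 1000. All the defensin genes lay under a common hESC H3K27me3 island of 244.6 kb, and background there was not tested. The excess of hTSC-only over hESC-only promoters depended on the calling. It was 537 against 661 among the upper 50% of islands by score per kb, 624 against 874 at equal covered length, and 745 against 801 when 50% of the promoter had to be covered.

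H3K27me3 overlapped 6116 promoters in hESC and 4422 in hTSC, although the islands covered more of the genome in hTSC. Of the hESC promoters 2861 (46.8%) were also called in hTSC, 3255 promoters were called in hESC only and 1561 in hTSC only. More promoters were called in hESC only than in hTSC only under every alternative tried. Many genes tied at 100% coverage in one cell type and 0% in the other and were ordered by score per kb; all those named here are at the score cap, so this order puts the narrowest islands first. With 100% in hESC and 0% in hTSC, the first 10 were GATA6, LOC124903317, LEKR1, DLX4, TFAP2A, OAF, HNRNPCL1, OR4K13, TBX2 and ZNF735. GATA6, DLX4, TFAP2A and TBX2 encode developmental transcription factors. With 0% in hESC and 100% in hTSC they were PRG3, the neighbours RAD51AP2 and VSNL1, PRKAG3, FABP1, SELL, CTLA4, CBFA2T3, C1QTNF9 and EPPIN, 6 of them on chromosomes 2 and 20. FABP1 encodes the liver fatty acid-binding protein, and SELL and CTLA4 encode proteins of leukocytes.

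Promoters with both marks in hESC, the state called bivalent, mostly went to H3K4me3 alone or stayed. H3K4me3 and H3K27me3 coincided at 5477 promoters in hESC and 2991 in hTSC. Away from coding gene ends, H3K4me3 islands also overlapped H3K27me3 more often in hESC. The shares were 56.4% and 61.6% for the upper and lower 50% of islands by score, against 26.9% and 31.5% in hTSC. A background shared by both hESC libraries was not excluded and could raise the hESC number. Over the 18690 promoters outside island-free stretches, the hESC number was 1.15 times that expected if the marks were independent and the hTSC number 0.858 times. Genes without H3K4me3 at either end had windows at both ends, where an H3K27me3 island is met more easily. Both ratios can be too low for this reason, so the hTSC value does not show that the marks avoid each other. Of the 5477, 2730 (49.8%) had H3K4me3 alone in hTSC, 2343 (42.8%) had both, 203 (3.71%) had H3K27me3 alone and 201 (3.67%) had neither. Promoters with H3K4me3 alone in hESC were stable, with 8416 of 9111 (92.4%) in the same state in hTSC. Among bivalent promoters without H3K4me3 in hTSC, coverage differed most in favour of hTSC at LRRC52 (5% in hESC and 97.0% in hTSC), KCNT1 and its neighbour SOHLH1 (10% and 100% each), SLC43A3 (11% and 95%) and RAET1E (16.1% and 100%). This ranking favours little H3K27me3 in hESC, where their islands were 1 to 3 kb wide. The scores were 19.6 at LRRC52, 12.9 at KCNT1 and SOHLH1, 8.91 at SLC43A3 and 2.19 at RAET1E, against a library median of 18.1. Most of these hESC calls were thus weak. The lists show both marks in a cell population and cannot show them on the same nucleosome.

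**Figure D5:**
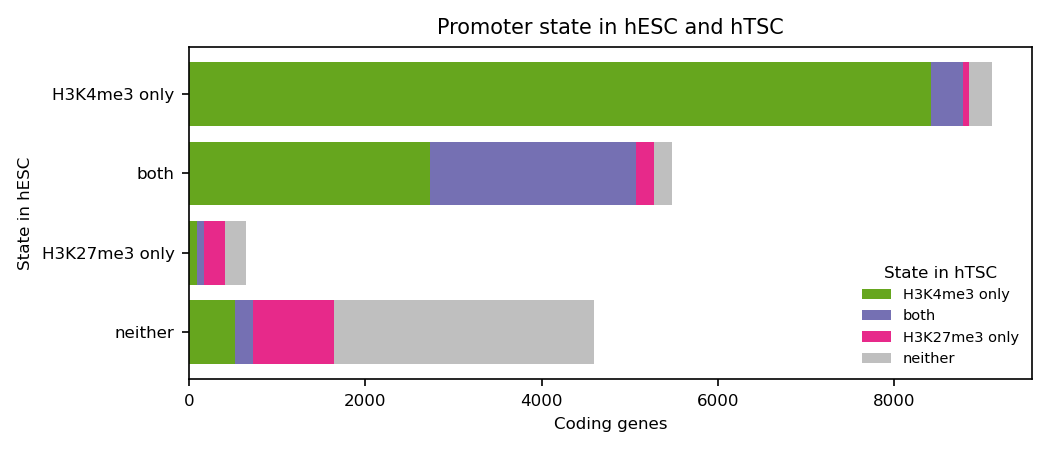
Number of coding genes by promoter state in hESC (bars) and hTSC (colours within bars). Of 5477 promoters with both marks in hESC, 2730 have H3K4me3 alone and 2343 both marks in hTSC, and of 9111 with H3K4me3 alone, 8416 are in the same state in hTSC.

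H3K4me3 width differed in opposite directions between gene lists. Among promoters marked in both cell types, the island was wider in hTSC at 25 of 30 trophoblast stem cell genes, and narrower at 18 of 19 pluripotency, 25 of 26 neuroectoderm, 17 of 18 mesoderm and 12 of 13 endoderm genes. These counts were not repeated with islands merged within 1 kb. Over 13852 promoters marked in both cell types the median width was 3.2 kb in hESC and 3.8 kb in hTSC, with a median log2 ratio of 0.19 (quartiles -0.15 and 0.58). The ratio was above 2-fold at 1611 promoters in favour of hTSC and at 767 in favour of hESC. The largest ratios in favour of hTSC were at P2RY6 (log2 ratio 4.12), ERVH48-1, which encodes an endogenous retroviral envelope protein (1.4 kb in hESC and 24 kb in hTSC, log2 ratio 4.10), SLC60A2 (3.87), TINCR (3.61) and TRPV2 (3.58). Those in favour of hESC were PAX7 (-4.39), the retinoic acid hydroxylase gene CYP26C1 (-4.17), LOC124908045 (9.6 kb in hESC and 0.6 kb in hTSC), LHX5 (-3.94) and UNCX (-3.74), of which PAX7, LHX5 and UNCX are homeobox genes. Islands of 5 kb or more lay over 2621 promoters in hESC and 4545 in hTSC, 1730 in common. With the widest 5% of islands in each library in place of 5 kb, the counts were 785 and 781, which this definition makes nearly equal by construction.

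Mean H3K27me3 coverage around all promoters was 14.5% in hESC and 15.9% in hTSC, a difference of 1.42 points. Its sign depended on the window and on trimming to equal covered length. These means are over all 19821 genes, and over the 18690 outside island-free stretches they were 15.4% and 16.9%. The difference was -4.29 points at equal covered length and -4.72 points with a 4 kb window. Over the 15266 genes with 1 chosen end, coverage was higher in hESC near that end and higher in hTSC farther out. The 1 kb just inside the gene had 28.4% in hESC and 18.6% in hTSC. At 9.5 kb outside the gene the values were 13.3% and 15.8%, and at 49.5 kb 11.3% and 16.5%. The sign therefore differs between short and long windows. Coverage was at least 25 points higher in hTSC at 2771 promoters and at least 25 points higher in hESC at 2100. Promoters with both marks in hESC went from a mean of 39.0% to 32.4%, and those with neither mark from 3.75% to 15.9% (4.89% and 21.0% outside island-free stretches). These groups were set by the hESC calls themselves, so part or all of this fall and rise can come from the grouping. Groups set by the state in hTSC were not compared.

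Islands shared between the cell types lay at coding gene ends more often than those of one cell type alone. Of the hESC H3K4me3 islands 24975 (53.2%) overlapped an hTSC island, against a median of 10.9% and a maximum of 11.5% when islands were moved along the chromosomes in 100 rotations. For hTSC islands the share was 39.6%, against a median of 7.89%. Coding gene ends were overlapped by 50.9% of shared and 5.56% of own H3K4me3 islands in hESC, and by 51.4% and 4.05% in hTSC. For H3K27me3 the values were 17.6% of shared and 11.5% of own islands in hESC, and 21.6% and 4.65% in hTSC. The median deposited score of H3K4me3 islands was 1000 for shared and 14.3 for own islands in hESC, and 272 and 13.2 in hTSC. H3K27me3 islands were shared less, 37.0% of them in hESC (rotated median 23.8%) and 26.5% in hTSC (18.1%). At equal covered length these shares were 19.3% and 38.8%. Within hESC, 54.6% of H3K4me3 islands overlapped H3K27me3 (rotated median 12.7%), and within hTSC 28.1% did (22.4%).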

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

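The tests of islands near the calling threshold, a shared background, single regions and reads matching alternate sequences, and the search of noncoding genes, were chosen only after the result was seen.

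Noncoding genes were outside the comparisons above, and 15706 of them lie away from coding gene ends. H3K4me3 was called in hTSC only at 2106 of them and in hESC only at 870, with 1941 in common. The input samples were not analysed here, so no control level stands beside these counts.

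Olfactory receptor genes, a control expected to lack both marks, had H3K4me3 at 78 and both marks at 74 promoters in hESC. Of the 78, 17.9% kept H3K4me3 among the upper 50% of islands by score, against 97.1% of other coding genes, so islands near the calling threshold may account for most of the H3K4me3. The same test argues against them for H3K27me3, which 90.4% of the 125 receptors that had it kept, against 80.3% of other genes. A background shared by both hESC libraries cannot be told apart: weaker islands away from gene ends overlapped H3K27me3 1.09 times as often as stronger ones in hESC (61.6% and 56.4%) and 1.17 times in hTSC, and no input was analysed here. A difference between the cell types themselves was not tested and stays open.

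Chromosomes 2 and 20 had more island length in hTSC for both marks, with hTSC to hESC ratios of 1.99 and 1.69 for H3K4me3 and 4.01 and 3.09 for H3K27me3, which were 1.61, 1.37, 1.86 and 1.43 times the median of the other chromosomes; chromosomes 13 and 18 came close to chromosome 20, at 1.497 and 1.52 and at 3.04 and 3.07, so chromosome 20 hardly stood apart by length. Broader calling in hTSC, in covered length, cannot be told apart, since at equal covered length by score per kb the same 4 values ran from 0.984 to 1.40, while by score the lowest was 1.10 and the highest 1.99. A candidate explanation is more copies of chromosomes 2 and 20 in hTSC: by median log2 width ratio over promoters they ranked 2 and 1 of 23, at 0.38 and 0.42, against a median of 0.17 over the others, while chromosomes 13 and 18 ranked 15 and 19. Chromosomes 22 and 19 ranked 3 and 4, at 0.32 and 0.26, although their H3K4me3 length ratios were both 1.03. Widths and lengths come from the same islands, so the width rank is not separate support for more copies. Single regions cannot be told apart from whole chromosomes, since the lowest share of 5 Mb bins above the genome-wide median was 61.5%. The inputs, which would show copy number, were not analysed here, so this remains a hypothesis, and a difference between the cell types was not tested.

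No island of either mark was called in any of the 4 libraries over 2556 kb of chromosome 6 (hg38, 29943601 to 32500000), a stretch of 108 coding genes that include POU5F1 and the tubulin gene TUBB. Chromatin without either mark is argued against, since in each of 17063 other runs of 108 neighbouring genes at least 25% had H3K4me3 in hESC. Reads that also match alternate sequences of this region, and so were not counted, cannot be told apart from other losses in processing, because the files hold 0 islands on sequences other than the chromosomes. The stretch was not the only one without islands. Others were 2446 kb of chromosome 5 with 25 coding genes, among them the pair SMN1 and SMN2, and 2799.6 kb at the start of chromosome X with 16. What these stretches have in common was not tested. Apart from the absence of both marks, no biological explanation was tested.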

How the results depend on the processing

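Leaving out blocks of dense H3K4me3 islands or chromosomes 2 and 20, ranking by score alone, both gene ends and the whole gene were alternatives chosen only after the result was seen. No paired analysis was possible because each group has 1 library, and nothing shows how far a repeat would move these values. Over all alternatives, 97 values of the comparisons were the same within their limits, 53 moved and 3 reversed. The limit was a factor of 1.5 for promoter counts and the mean coverage difference, and the 95% binomial interval for shares. Only the mean coverage difference could be called reversed. A change in which of 2 counts was larger, as for H3K4me3 in hTSC only and hESC only, was not called so. Of the list results 499 kept their side of the middle 95% of random lists, 41 moved outside it, 24 moved inside it and 8 reversed from outside it. Lists inside it were given no direction, and their differences changed sign in 35 results, 33 of which stayed inside. Of the gene values 3067 were the same, 730 moved and 27 reversed, where a reversal needed at least 5 points or 0.3 on the log2 scale in the reported value. More promoters had H3K27me3 in hESC only than in hTSC only under every alternative run, and the trophoblast stem cell list stayed outside the random lists for both marks. Any annotated start site of each gene was not run, since the annotation gives no transcripts. The cause was not tested where none is given. Depth is unknown and limits which weak islands were called.

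The shares of islands overlapping the other cell type were 53.2% (hESC) and 39.6% (hTSC) for H3K4me3 and 37.0% and 26.5% for H3K27me3. In the same order they were 74.3%, 56.1%, 27.3% and 20.5% for the upper 50% of islands by score per kb, and 74.2%, 56.0%, 30.5% and 23.2% by score. At equal covered length they were 47.6%, 50.3%, 19.3% and 38.8% by score per kb and 46.2%, 56.2%, 16.5% and 56.5% by score; trimming a library leaves fewer islands there to be met. With 50% of the island overlapped they were 48.8%, 34.1%, 31.9% and 12.2%, and with islands merged within 1 kb 57.8%, 41.3%, 37.4% and 29.1%. For islands of 1 kb or more H3K4me3 shares were 54.4% and 41.0%. Without dense blocks they were 57.5% and 37.8%, and 25.3% for hTSC H3K27me3; without chromosomes 2 and 20 they were 52.7% and 41.3%, and 35% for hESC H3K27me3.

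Promoters with H3K4me3 in hTSC only numbered 537 for the upper 50% by score per kb and 582 at equal covered length by score. H3K27me3 in hTSC only was at 800 promoters at equal covered length by score per kb and 669 by score, and both marks in hTSC at 1979 and 1670. Over whole genes, H3K27me3 in hESC only was at 4958 genes, and both marks at 8810 in hESC and 4922 in hTSC, since the window is longer. The share of promoters with both marks in hESC that had H3K4me3 alone in hTSC was 52.7% for the upper 50% by score per kb, 60.5% and 64.3% at equal covered length by score per kb and by score, 48.1% with 500 bp to either side and 43.8% with 50% of the promoter covered. The widest 5% of islands lay over 785 promoters in hESC and 781 in hTSC, by construction near each other.

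The mean difference in H3K27me3 coverage around promoters, 1.42 points, was -4.29 and -4.83 points at equal covered length by score per kb and by score, and -4.72 points with a 4 kb window. It was 3.96 points with 100 kb, 2.42 with both gene ends, 3.02 over whole genes, 2.68 without dense blocks and 0.717 without chromosomes 2 and 20. Over all genes coverage was higher in hESC near the promoter and in hTSC farther out, so short and long windows need not share a sign. Lists outside the random lists that reversed in mean H3K27me3 difference were HOX at 12.2 points for the upper 50% by score per kb, where capped scores rank wide islands low, and olfactory receptors at 2.88 points without dense blocks. With a 100 kb window they were neuroectoderm at 21.5, mesoderm at 15.5, the WNT, TGF-beta, BMP and FGF list at 0.193, forkhead at 10.4 and T-box at 3.54 points, and over whole genes mesoderm at 0.0292 points. Sign changes of lists inside the random lists included LHX and LMX genes at 15.99 points with 100 kb, PAX genes at -8.57 and keratins at -11.7 points at equal covered length by score per kb, and SOX genes at -3.29 and endoderm at -11.2 points with 4 kb.

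Genes reversed in H3K27me3 coverage difference as follows. For the upper 50% by score per kb HOXC11 was at 23 and HOXC13 at 45.9 points. At equal covered length CRIPTO was at -13.1 by score per kb and -20.3 by score, and PAX7 at -93 by score per kb. With 100 kb CDX2 was at 1.92, GRB10 at 3.45, LEP at 5.23, LHX5 at 34.3 and MMP2 at 13.2 points. With both gene ends CYP19A1 was at 22, EXOC6 at 1.43 and LHX5 at 7.37 points, and over whole genes GATA4 was at -8.48 and LHX5 at 7.37 points. In log2 H3K4me3 width, with 200 bp added to each width, the reversed genes were DLX4 at -0.047, HOXD13 at -1.51, TBX2 at -0.58, TBX3 at -1.06 and TFAP2A at -0.048 with islands merged. Over whole genes they were AEBP2 at -0.12, DLK1 at 0.42, ITGA1 at 0.30, KCNT1 at 0.32, PSG1 at 0.52 and PSG3 at 0.064, where islands inside the gene count, and SELL was at -2.00 at equal covered length by score.

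Over all alternatives the mean H3K27me3 difference of each list, in points, ranged as follows: pluripotency 6.36 to 16.1, trophoblast stem cell -46.5 to -11.4, syncytiotrophoblast -29.1 to -11.7, extravillous trophoblast -24 to 0.379, amnion -24 to 1.40, neuroectoderm -29.1 to 21.5, mesoderm -20.3 to 15.5, endoderm -11.2 to 27.5, blood and endothelium 9.91 to 20.8, stromal 0.0727 to 13, germline 8.76 to 18.9, imprinted -18 to 1.11, housekeeping -0.353 to 1.51, polycomb and trithorax -23.7 to -8.11, signalling -25 to 0.193, HOX -62.7 to 12.2, olfactory receptors -26 to 2.88, ZNF -28.6 to -12.2, protocadherins -15.7 to -2.09, keratins -11.7 to 4.91, histones -5.50 to -0.980, SOX -3.29 to 12.3, forkhead -11.3 to 10.4, T-box -20 to 3.54, PAX -8.57 to 30.7, LHX/LMX -24.4 to 16. For H3K4me3 they were pluripotency -37.9 to -20.9, trophoblast stem cell 12.2 to 20.5, syncytiotrophoblast 25 to 46.5, extravillous trophoblast -1.42 to 7.75, amnion 0.225 to 14, neuroectoderm -21.6 to -6.05, mesoderm -22.9 to -15, endoderm -9.48 to -6.66, blood and endothelium -17.6 to 0.00462, stromal -20.7 to 3.03, germline 3.68 to 27, imprinted -2.13 to 7.01, housekeeping -0.750 to 6.36, polycomb and trithorax -3.78 to 4.03, signalling -8.70 to -4.32, HOX -25.8 to -13.9, olfactory receptors -12.6 to -0.218, ZNF 1.22 to 7.77, protocadherins -3.32 to 8.17, keratins 3.39 to 6.06, histones -3.44 to 3.41, SOX -12.3 to -0.703, forkhead -10.4 to -2.39, T-box -16.5 to -6.49, PAX -28.7 to -6.13, LHX/LMX -32.5 to -12.2. Of the 41 results that moved outside the random lists 17 were for H3K27me3, 5 of them LHX and LMX genes and 3 protocadherins, and 24 for H3K4me3, 8 of them T-box genes. Of the 24 that moved inside, 6 were germline H3K4me3 and 3 each signalling and T-box H3K27me3.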

Other observations

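The split of ZNF genes by chromosome, the noncoding genes named here and the TP63 region were chosen only after the result was seen. ZNF genes, a large family of zinc finger transcription factors, were mostly free of H3K27me3 in hTSC. Of 498 measured, 187 had H3K27me3 at the promoter in hESC and 54 in hTSC, with 149 in hESC only and 16 in hTSC only, and 122 went from both marks to H3K4me3 alone. H3K4me3 was called at 467 and 466, with median widths of 3 kb in hESC and 4.2 kb in hTSC. Mean H3K27me3 coverage was 32.4% and 8.37% (percentile 0). ZNF354A and ZNF404 had 100% in hESC and 0% in hTSC. For the 242 ZNF genes on chromosome 19, where the family is clustered, the means were 37.5% and 5.54%, against 20.3% and 15.2% for 1118 other coding genes of that chromosome and 27.4% and 11.1% for 256 ZNF genes elsewhere. Without dense blocks the family's difference was -12.2 points in place of -24.0.

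Noncoding genes known from stem cells or placenta went in several directions. MIR302CHG, the host transcript of a microRNA cluster of pluripotent cells, had a 10.2 kb H3K4me3 island in hESC and none in hTSC. The pluripotency transcripts ESRG and LINC-ROR had H3K4me3 in hESC only, 12.4 and 2.2 kb, with H3K27me3 coverage of 19.5% and 11% in hESC and 89.9% and 100% in hTSC. LNCPRESS2 had 14.8 kb in hESC only. MIR512-1, at one end of the placental microRNA cluster of chromosome 19, had a 20.6 kb island in hTSC only, MIR371A had 0.8 kb in hESC and 9 kb in hTSC, and MIR30D had 31.8 kb in hTSC only. MIR205HG had 5.8 kb in hESC and 7.6 kb in hTSC, and MIR517A, of the placental cluster, and the imprinted H19 had no H3K4me3 island in either. Inside TP63, which encodes p63 of epithelial and trophoblast progenitors, an H3K4me3 island of 4.8 kb at the score cap (hg38, chromosome 3, 189788801 to 189793600) was called in hTSC, away from the outer gene ends used as promoters.

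Developmental transcription factor families had H3K4me3 in both cell types, with narrower islands in hTSC. SOX genes, 19 in number, had H3K4me3 at 18 in each and median widths of 8.5 and 4.2 kb, and mean H3K27me3 coverage was 42.3% in hESC and 50.04% in hTSC (percentile 36.9), with a difference of -3.29 points in a 4 kb window; SOX11 had 11% and 100%. The 9 PAX genes had coverage of 88.4% and 90.9% (percentile 11.5), with differences from -8.57 points (equal covered length by score per kb) to 30.7 points (100 kb), and median widths of 9.7 and 4.6 kb. The 9 LHX and LMX genes had 84.2% and 77.3% (percentile 3.26) and widths of 12 and 4.2 kb; their difference of -6.98 points was outside the middle 95% in 5 alternatives, down to -24.4 points at equal covered length by score, but 15.99 points with 100 kb. LHX3 had a 10 kb H3K4me3 island in hESC and none in hTSC. The 15 T-box genes had coverage of 70.4% and 53.7% (percentile 0.15), and TBX2 and TBX4 went from 100% and 95.1% to 0%. The 45 forkhead genes had 51.5% and 46.2% (percentile 0.21), with FOXP4 at 100% and 7.1%. Neither of these calls held with a 4 kb window. The differences there were nevertheless larger, at -20 points for T-box and -11.3 points for forkhead genes, against -16.7 and -5.33. The T-box call also ended with both gene ends and over whole genes, and the forkhead call with random lists that were not matched. For both families the direction turned with a 100 kb window, to 3.54 points for T-box and 10.4 points for forkhead genes.

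Keratins, the intermediate filament genes of epithelia, had H3K4me3 at 8 of 45 in hESC and 12 in hTSC, among them KRT80 with 5.4 kb in hTSC only, and H3K27me3 coverage of 12.5% and 14.6% (percentile 72.0), with a difference of -11.7 points at equal covered length by score per kb and 4.91 points, outside the random lists, with 4 kb. Clustered protocadherins, neuronal adhesion genes, had H3K4me3 at 43 of 53 in each cell type, 8 of them in hESC only and 8 others in hTSC only, and coverage of 8.75% and 4.69% (percentile 15.0). That difference of -4.06 points was -10.8 points with 100 kb, -11.9 with both gene ends and -15.7 over whole genes, outside the middle 95% of random lists each time. Histone genes had H3K4me3 at 61 of 73 in hESC and 62 in hTSC, and coverage of 4.57% and 3.28% (percentile 20.2), but outside the random lists with 100 kb (-5.50 points). H1-0, which its symbol placed in this family although its product is a replication-independent linker histone, went from 55.8% to 0%.

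Germline genes had H3K4me3 at 5 of 13 in hESC and 10 in hTSC, with mean promoter coverage of 25% and 52.0% (percentile 98.2). SYCP1, of the meiotic synaptonemal complex, and PIWIL1, of the piRNA pathway, had islands of 2.6 and 1.6 kb in hTSC only, together with H3K27me3 coverage of 96% and 74.3% there and 0% in hESC. The H3K4me3 call for this list ended in 6 alternatives, for example with a difference of 16.7 points at equal covered length by score per kb. The list's H3K27me3 coverage was 18.6% and 32.8% (percentile 86.9). Imprinted genes had H3K27me3 at 13 of 17 in hESC and 7 in hTSC, and coverage of 37.6% and 32.1% (percentile 8.69), with differences from -18.0 points (4 kb window) to 1.11 points (100 kb). PEG3 and GRB10 went from 100% and 46% to 0%, though GRB10 differed by 3.45 points in favour of hTSC over 100 kb, while DLK1 went from 32% to 100%. Among markers of other cell types, the endothelial genes KDR and ERG had H3K27me3 coverage of 8% and 15% in hESC and 100% in hTSC, whereas FLI1 had 76% in hESC and 0% in hTSC. The fibroblast marker THY1 had 8% and 68.9%, and the intermediate filament gene VIM 20% and 91.2%.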
